A study of Homo sapiens with 4 samples.

How the data were processed

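Total RNA of K562 cells was profiled on 4 Illumina expression bead arrays, 2 arrays from a stable line with a control short hairpin RNA and 2 from a stable line with a hairpin against KLF3. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled with Illumina's amplification kit. The series' design text describes duplicate profiles of each line and the second array of each group carries the word Repeat. Nothing in the labels says that the duplicates were separate cultures or separately derived lines, so p-values measure only the spread between these arrays, which may be technical, and each group stands for 1 line.

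The deposited scanner table held 47322 probes with a mean intensity and a detection p-value for each array. The deposited intensities were linear, had not been normalized between arrays and had not been background-subtracted, since undetected probes sat well above 0 and the 4 medians lay between 136 and 140. The deposited detection p-values moved in steps of 1 in 770, the number of negative-control bead types that such steps imply. A second deposited table, the authors' processed intensity values, kept the rank order of the scanner values on every array (Spearman correlation of 1) and had the same sorted values on all 4 arrays within 0.302%, as quantile normalization gives. Its array medians were 138.527, 138.522, 138.524 and 138.506, on a linear scale without centring or background subtraction, and its software is not given in the sources used here.

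Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal background and an exponential signal, takes the negative-control level from the detection p-values, adds an offset of 16 and applies quantile normalization before log2. Log2 fold changes are therefore on a scale of corrected signal plus offset and understate changes of dim genes. Probes were kept where the detection p was under 0.01 on both arrays of at least 1 group, which left 15722. Gene names came from the platform annotation given with the series, updated by gene identifier through a table of human genes of assembly GRCh38.p14. Of all probes, 30112 had 1 symbol, 8 had several and 17202 were not listed there and are unnamed here; 30073 of the symbols matched by identifier. Kept probes with 1 symbol numbered 12461, and the probe with the highest mean over the 4 arrays stood for each gene, giving 9530 genes. The assembly table also gave each gene's chromosome and its neighbours for 9520 genes; no coordinates were used in the text.

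The KLF3 knockdown arrays were compared with the control arrays in 1 limma model without covariates (lmFit and eBayes without an intensity trend, two-sided, 2 residual degrees of freedom and 4.33 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 9530 genes and a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333. A gene not detected on either array of a group has only a bound there. Its fold is given as at least the ratio of the brighter group's mean to the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among detected probes, and no fold is given where both groups were undetected. Standard errors are those of the limma fit, and errors after ± are standard deviations over the 2 arrays of a group.

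Before the data were examined, 37 gene lists were written from general knowledge of K562 cells and of other cell types, with 932 entries, 925 of which matched a current symbol. The 34 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With 2 residual degrees of freedom the estimated correlation gave no list under the threshold, the smallest adjusted p being 0.503. Camera then refers its statistic to these 2 degrees of freedom, so a list could hardly pass. For the BCR-ABL and STAT5, histone and adhesion lists the estimated correlations were -0.027, -0.0014 and 0.009, under the preset value. Correlation between genes is therefore not why these lists missed the threshold. For the globin and red cell membrane lists it was 0.097 and 0.076, and the reasons cannot be told apart. Counts of list members are given over all genes and adjusted over the list alone. The genes named were fixed by rule before the data were examined: KLF3, KLF1, KLF8 and LGALS3; changed members of the KLF family and KLF3 partner lists; the 12 largest increases and the 12 largest decreases among changed genes whose groups did not overlap; up to 4 members with the smallest adjusted p of each list that passed or held at least 3 changed genes; and HBG1, HBG2, HBE1, HBZ and GATA1. A further gene of the rule is not reported here. Loci without a proper name were counted and not named. Other list members that are named were chosen after their values were seen.

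Alternatives to the background correction, offset, normalization, source of values, detection filter, choice of probe, variance model, replicate block and threshold were fixed before the data were examined, as was leaving out each array. A run without chromosome 16 and without blocks of shifted neighbouring genes was added after seeing the data. Such blocks were sought with a sliding median over 31 measured neighbours, against the 95% point of the extreme windows of 1000 permuted gene orders. A window of 30 genes was used at first and gave 1 block fewer.

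The scripts were tested on simulated signals for the real probes, with noise taken from the differences between real replicate arrays. The noise on the log scale came from the brighter kept probes only. Simulated replicate differences had a standard deviation of 0.159, against 0.172 in the real control pair and 0.211 in the real knockdown pair. The rates below may therefore be better than those of the real arrays. In 10 runs with 200 changed genes each, and a median of 10602 genes tested, 4.18% of the genes changed by 1.25-fold were called, 70.0% at 1.5-fold, 94.1% at 2-fold and 98.5% at 4-fold. Fitted log2 changes were 0.933 of the simulated ones at 2-fold, and 8.61% of the calls were false, above the nominal rate. With 3656 changed genes among 11111 tested, 7.18% of 2241 calls were false. An earlier simulation counted background noise more than once and called fewer genes. Without simulated changes no gene, list or block was called, a list shifted by 0.5 on the log2 scale was the sole list called, and a block of 81 neighbours shifted by 0.4 was found whole, with 12 further genes. The array number limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.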

Results

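The series measured gene expression in K562, a human erythroleukemia line derived from chronic myeloid leukemia in blast crisis that carries the BCR-ABL fusion and makes embryonic and fetal globins. A stable line with a hairpin against KLF3, a transcriptional repressor of the Krüppel-like factor family, was set against a stable line with a control hairpin, with 2 arrays for each. The comparison addresses which transcripts differ when KLF3 is depleted. Detected probes numbered 16182 and 15934 on the control arrays and 15479 and 15534 on the knockdown arrays. The log2 values of replicate arrays correlated across genes with r = 0.997 in the control group and 0.995 in the knockdown group, and arrays of different groups with r between 0.971 and 0.972. The standard deviation of the difference between replicate arrays was 0.16 and 0.20 on the log2 scale, against 0.47 to 0.48 between groups.

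KLF3 itself could not be measured. Both of its probes were not well above background on any array. One gave an intensity of 136 ± 9.76 in the control group and 139 ± 0.265 in the knockdown group (SD, n = 2), and the other 122 ± 5.33 and 124 ± 4.68. These arrays therefore give no check of the depletion or of the labels. KLF8 and LGALS3, reported KLF3 targets in other cells, and C1QTNF12 were also not well above background in either group. Of the 4 measured genes on the list of KLF3 targets and partners, FHL3, a LIM-domain partner of KLF3, fell by 0.62 (SE 0.09, limma adjusted p = 0.0036), while CTBP1, CTBP2 and WDR5 did not pass.

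In the KLF3 knockdown line globins and other red cell genes were higher, whereas KIT, EGR1, STAT5A and several adhesion genes were lower. The globin, red cell membrane, BCR-ABL and STAT5, and adhesion lists passed camera at a preset correlation, but no list passed with an estimated correlation (adjusted p = 0.503 for these 4). The latter run rests on 2 residual degrees of freedom, on which a list could hardly pass, so it does not decide against these shifts. The embryonic globin HBZ was 4.76-fold higher and the embryonic globin HBE1 3.58-fold higher. The monocarboxylate transporter gene SLC16A9 was at least 18.7-fold higher, and the neuropeptide gene NTS, encoding neurotensin, was at least 9.67-fold lower. Folds and bounds hold on the background-corrected scale: without background correction the log2 differences of SLC16A9 and NTS were 2.995 and -1.94, smaller than these bounds, and those of all 156 genes named by rule were smaller, 30 of them by more than 1.5 times in fold. Across the 9530 genes tested, 1845 rose and 1971 fell (limma, Benjamini-Hochberg adjusted), 40.0% of the genes together. Fitted differences were at least 2-fold for 153 higher and 164 lower genes and at least 4-fold for 26 and 23; with genes undetected in 1 group at their bound, the counts were 136 and 135 at 2-fold and 17 and 17 at 4-fold. Leaving out 1 control array lowered the total of 3816 to 1759 without replicate 1 and to 1720 without replicate 2. Scaling to the median in place of quantile normalization gave 1286 higher and 2150 lower genes, so that 37.4% of the changed genes were higher in place of 48.3%.

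The 12 largest increases in fitted fold reached adjusted p of 0.000352 or less in limma. The rank of a gene undetected in the control group rests on a fitted value against background, and HBZ, outside the 12 but detected on every array, rose by more than the bounds of several of them. HINT3, a histidine triad nucleotide-binding protein gene, was 11.5-fold higher, with normalized log2 signals of 7.11 ± 0.00 in the control group and 10.64 ± 0.08 in the knockdown group (SD, n = 2). BPNT1, a bisphosphate nucleotidase gene, was 8.60-fold higher, TSPAN18, encoding a tetraspanin, 6.84-fold, and SEMA4D, encoding a semaphorin, 6.10-fold. Without background correction the log2 increases of HINT3, BPNT1, TSPAN18 and SEMA4D were 2.70, 1.86, 1.41 and 1.246 in place of 3.53, 3.10, 2.77 and 2.61. HINT3 had 2 kept probes, and with their mean its increase was 1.81. The 2 probes thus disagreed, and the 11.5-fold rise rests on 1 of them. The other 8 genes were not well above background on either control array. Among them, CA1, the carbonic anhydrase of red cells, was at least 5.21-fold higher and STXBP6, a syntaxin-binding protein gene, at least 5.16-fold. ADGRV1, CNRIP1, ACSS1, GNG11 and SH3GL3 were at least 4.31-fold, 4.13-fold, 4.05-fold, 3.98-fold and 3.63-fold higher. Without background correction the log2 increases of these 7 genes lay between 1.02 and 1.26, under their bounds; with the mean of its probes that of CNRIP1 was 1.86, also under its bound.

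The 12 largest decreases in fitted fold were in the majority genes that the knockdown arrays did not detect, so that their rank, too, rests on values against background. PLXNA1, chosen after its value was seen and detected on every array, was 4.33-fold lower, beyond the bounds of several of the 12. IGF1, the insulin-like growth factor gene, was at least 4.48-fold lower on the probe used and ABCA1, the cholesterol efflux transporter, at least 4.25-fold. IGF1 had 2 kept probes, and their mean gave a log2 change of -2.38 in place of -3.17. Without control replicate 1 the IGF1 change was -1.65 and without control replicate 2 it was -1.49. The probe used read 7.62 and 7.90 on the control arrays, so spread between those arrays does not account for these values. The probe was chosen anew in each run, and these values point to the other IGF1 probe. MS4A3, a myeloid membrane protein gene detected on every array, was 5.87-fold lower, from 9.50 ± 0.09 to 6.95 ± 0.02 on the log2 scale (SD, n = 2); without background correction the log2 change was -1.77. ARAP3 was lower as well (limma adjusted p = 3.84e-05), but 1 of the 2 knockdown arrays did not detect it, so no exact fold is given. CAVIN2, a caveola component, was at least 5.41-fold lower and lies in a block of chromosome 2 whose genes were lower together. PLEKHH2 and the transcription factor gene FOXA2 were at least 3.19-fold and 3.06-fold lower. VCX, VCX3A and VCX3B were at least 3.61-fold, 4.67-fold and 4.13-fold lower, but they are near-identical X-linked germline genes whose probes cannot be assigned with certainty, and FCGR1A, at least 4.15-fold lower, has near-identical copies as well. Without background correction the log2 decreases of the 9 genes other than NTS with a bound lay between 0.94 and 1.38, under their bounds.

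**Figure D1:**
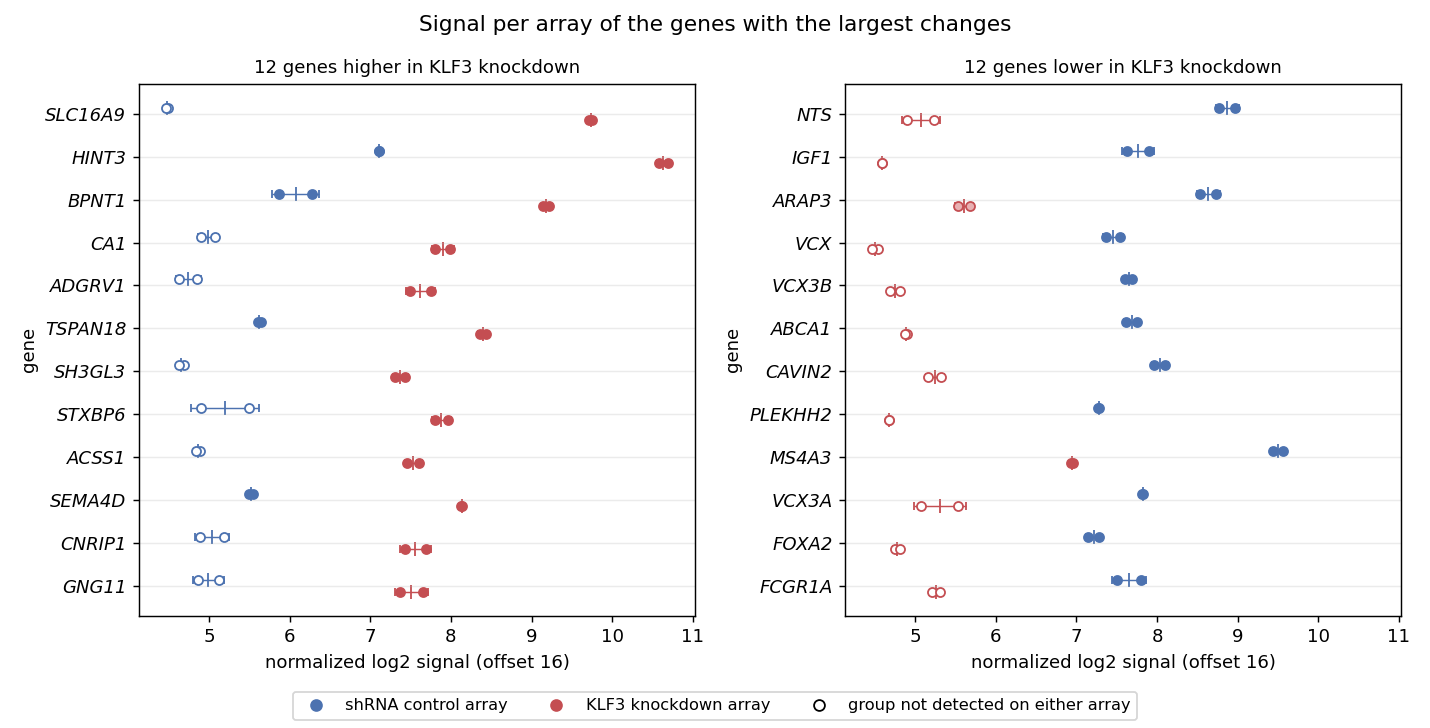
Normalized log2 signal on each array for the 12 genes with the largest increase and the 12 with the largest decrease, with blue circles for control arrays, red circles for knockdown arrays, and ticks with bars for the mean and SD of 2 arrays. Open circles mark a group detected on neither array and pale circles a group detected on 1. The groups did not overlap for any gene. HINT3, detected on every array, rose from 7.11 to 10.64 on the probe drawn, with which its other kept probe disagreed.

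Globin genes were higher as a group. Of the 9 measured, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 1.41 (camera adjusted p = 2.45e-06; adjusted p = 0.503 with an estimated correlation). HBZ rose by 2.25 (SE 0.08), HBE1 by 1.84 (SE 0.10), HBA1 by 1.60 (SE 0.09) and HBA2 by 1.41 (SE 0.08), with limma adjusted p between 3.84e-05 and 0.000169. The fetal globin gene HBG1 rose by 0.54 (SE 0.09, limma adjusted p = 0.00501), and HBG2 differed by 0.28 (SE 0.09, limma adjusted p = 0.0518), short of the threshold. HBG1 and HBG2, like HBA1 and HBA2, are near-identical copies whose signals cannot be separated with certainty. The adult globin genes HBD and HBB rose as well, HBB from a level not well above background in the control group. The 4 alpha-like genes HBZ, HBA1, HBA2 and HBQ1 lie on chromosome 16, where genes were higher in general. The 5 other globins had a median of 0.79 and 4 of them rose. That median is the fitted value of HBB, which was at least 1.33-fold higher. With HBB at this bound the median is the 0.54 of HBG1. HBM and AHSP, the alpha-globin chaperone gene, were not well above background.

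Red cell membrane genes were also higher, with 9 of 14 measured members up and 0 down (11 and 0 adjusted over the list alone), and a median of 0.74 (camera adjusted p = 3.66e-05; adjusted p = 0.503 with an estimated correlation). ERMAP, encoding an erythroid membrane-associated protein, rose 3.59-fold and TMOD1, encoding the actin-capping protein tropomodulin, 1.80-fold. RHCE and RHD, the near-identical Rh blood group genes, rose 2.98-fold and 2.75-fold, with probes that cannot be assigned with certainty; without background correction the log2 change of RHD was 0.61 in place of 1.46. None of the 14 lies on chromosome 16. Among heme synthesis and iron genes, 10 of 18 rose and 1 fell (10 and 1 adjusted over the list alone), but the list did not pass camera (median 0.35, adjusted p = 0.0652; 0.503 with an estimated correlation). It passed fry, which tests whether a list's genes move one way and not whether they differ from other genes (adjusted p = 0.0139). ALAS2, the erythroid enzyme of the first step of heme synthesis, rose 2.27-fold, PPOX 2.09-fold, FECH, which inserts iron to form heme, 1.83-fold and UROS 1.66-fold. TFRC, the transferrin receptor gene, fell by 0.60 (SE 0.08, limma adjusted p = 0.00269). SLC4A1, the band 3 anion exchanger gene, was not well above background.

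Regulators of the erythroid program moved both ways. GATA1 differed by -0.14 (SE 0.08, limma adjusted p = 0.218). GATA2 fell by 0.71 and ETV6 by 0.83, whereas BCL11A, a repressor of fetal globin genes, rose by 0.82 and E2F4, on chromosome 16, by 0.63. Of 21 measured erythroid transcription factor genes, 7 rose and 7 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.651). Within the KLF family 3 genes rose and 4 fell of 11 measured (3 and 5 adjusted over the list alone; camera adjusted p = 0.856). KLF1, the erythroid activator, rose 1.41-fold (limma adjusted p = 0.00787), KLF2 1.48-fold and SP3 1.29-fold, and KLF6, KLF10, KLF13 and SP2 fell by 0.57, 0.55, 0.56 and 0.41 on the log2 scale. Without control replicate 2 the KLF1 change did not pass (log2 fold change 0.46, limma adjusted p = 0.0653), nor did KLF2, KLF13, SP2 and SP3, with adjusted p of 0.0659, 0.109, 0.0745 and 0.0761. Without control replicate 1 the limma adjusted p of KLF2, KLF6, KLF10, KLF13, SP2 and SP3 were 0.059, 0.0643, 0.0706, 0.0678, 0.111 and 0.0878, and without knockdown replicate 2 that of SP2 was 0.0622.

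Genes of BCR-ABL and STAT5 signalling were lower as a group, with 0 of 22 measured up and 12 down (2 and 12 adjusted over the list alone). The median was -0.39, or -0.26 with undetected genes at their bound (camera adjusted p = 0.00509; adjusted p = 0.503 with an estimated correlation). The other 10 genes did not pass over all genes, among them ABL1 (0.02), BCR (-0.18), JAK2 (-0.11) and SOCS2 (-0.05). DUSP6, 1 of the 12, was undetected in the knockdown group, with a bound of 1.01-fold. STAT5A fell by 1.16 (SE 0.08), the kinase gene PIM2 by 1.19 (SE 0.08) and the feedback inhibitor gene SOCS1 by 0.90 (SE 0.09), the last against the direction of most chromosome 16 genes around it. IGFBP4 was at least 1.60-fold lower, but its log2 change without background correction was -0.37, smaller than that bound. The stem cell factor receptor gene KIT fell by 1.95 (SE 0.08, limma adjusted p = 5.34e-05), or 3.87-fold, and by 1.15 without background correction. Of 21 immediate early and MAPK feedback genes, 3 rose and 10 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.0674; fry adjusted p = 0.0139, down). EGR1 fell by 1.80, IER3 by 1.06 and SPRY4 by 1.04, and PHLDA1 rose by 0.85.

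Actin and adhesion genes were lower, with 0 of 30 measured up and 13 down (0 and 13 adjusted over the list alone), and a median of -0.28 (camera adjusted p = 0.0192; adjusted p = 0.503 with an estimated correlation). CD44, the hyaluronan receptor gene, was 2.58-fold lower, LGALS1, encoding galectin-1, 2.56-fold and MYH9, a non-muscle myosin heavy chain gene, 1.73-fold. ITGAV, an integrin gene 1.97-fold lower, lies in the shifted block of chromosome 2. Without chromosome 16 and the shifted blocks this list did not pass (camera adjusted p = 0.0524). Histone genes were higher by a small amount, 9 of 24 up and 0 down (9 and 1 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0119; adjusted p = 0.503 with an estimated correlation). H2BC21, H4C14, H2AC18 and H3C4 rose by 0.69, 0.70, 0.62 and 0.58, though histone genes have close copies whose probes cannot be assigned with certainty.

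**Figure D2:**
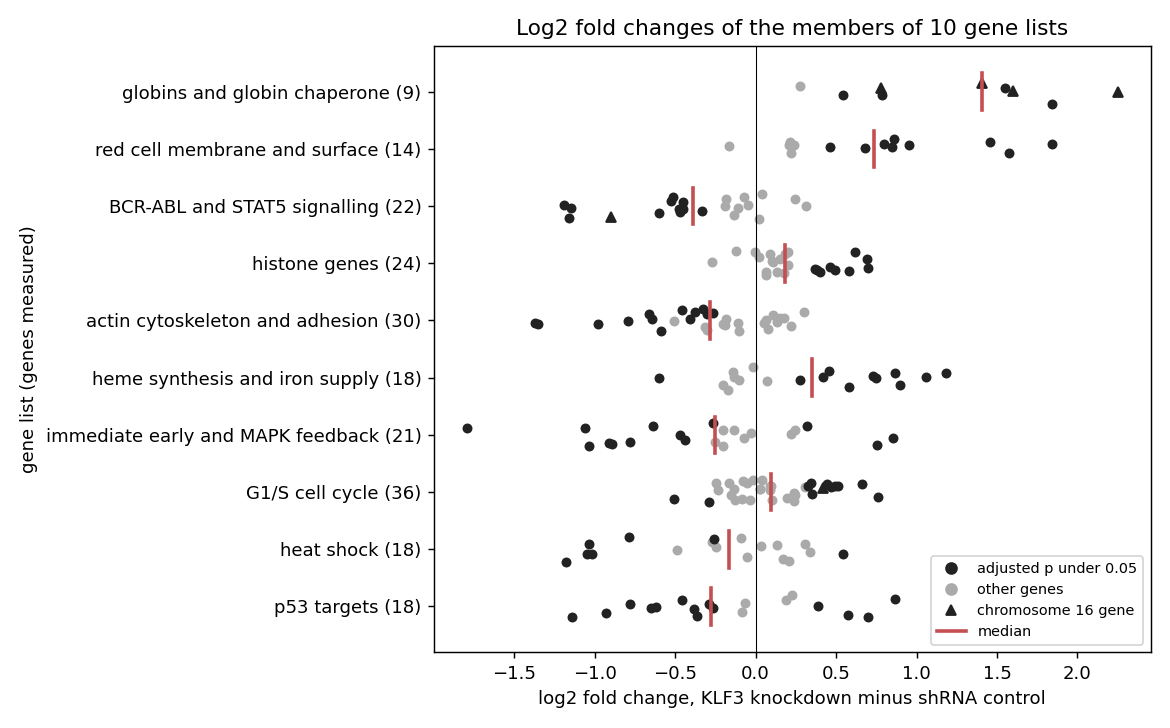
Log2 fold change of each measured member of 10 gene lists, as circles or, for chromosome 16 genes, triangles, dark where the limma adjusted p was under 0.05 and grey otherwise, with the list median as a red bar. The globin median was 1.41, the red cell membrane median 0.74 and the BCR-ABL and STAT5 median -0.39.

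Proliferation and stress lists did not pass camera but held changed genes. Among heat shock genes 1 rose and 6 fell of 18 measured (1 and 9 adjusted over the list alone; camera adjusted p = 0.217; fry adjusted p = 0.0357, down), with DNAJB1, HSPA8 and DNAJA1 lower by 2.27-fold, 2.07-fold and 2.05-fold and HSPA1A, which has a near-identical copy, by 1.72-fold. Among p53 targets 4 rose and 10 fell of 18, over all genes and adjusted over the list alone (camera adjusted p = 0.358), with CDKN1A, the p21 cell cycle inhibitor gene, 2.20-fold lower, TP53INP1 1.90-fold lower, TP53I3 1.72-fold lower and SESN1 1.82-fold higher. Of 18 genes of cyclins, their kinases and inhibitors 6 rose and 2 fell, with both adjustments (camera adjusted p = 0.44): the inhibitor gene CDKN1C rose 2.34-fold, CDKN2D fell by 0.74 and CDK6 rose by 0.62. Of 36 G1/S genes 10 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.152; fry adjusted p = 0.0139, up), including NASP at 0.76, TYMS at 0.51 and FEN1 at -0.51, the last not passing without control replicate 1 (-0.48, limma adjusted p = 0.0523). Of 49 G2/M genes 11 rose and 7 fell with either adjustment (camera adjusted p = 0.725), with TUBB4B, a tubulin gene, 2.34-fold lower. Among 26 apoptosis genes 4 rose and 10 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.44; fry adjusted p = 0.038, down). Outside chromosome 16 and the shifted blocks the 23 remaining members had a median of 0.0019, with 4 higher and 8 lower (camera adjusted p = 0.846). CFLAR, an inhibitor of death receptor signalling, was 2.05-fold lower and CASP8 at least 1.36-fold, both in the shifted block of chromosome 2, and BMF was at least 1.72-fold and CASP9 1.57-fold lower; without background correction the log2 changes of CASP8 and BMF were -0.27 and -0.39, smaller than their bounds.

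Metabolic lists did not pass camera, although 3 lists of this paragraph passed fry. Of 20 glycolysis genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0705; fry adjusted p = 0.0139, up), with PFKFB4 2.06-fold higher, ALDOA, on chromosome 16, 1.73-fold higher, and PFKFB3 1.44-fold lower. INSIG1, a sterol sensor gene, rose 2.35-fold and 5 of 16 cholesterol synthesis genes rose against 1 that fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.152; fry adjusted p = 0.0312, up). ACSL4, a fatty acid activating enzyme gene, fell by 1.22. CAT, encoding catalase, rose 2.45-fold, and PGD, of the pentose phosphate pathway, fell by 0.72. Of 38 oxidative phosphorylation genes 10 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.221), and NDUFB10 and UQCRC2, up by 0.89 and 0.65, lie in shifted blocks of chromosome 16. Ribosome biogenesis and MYC targets held 10 genes lower and 1 higher of 32 (7 and 1 adjusted over the list alone; camera adjusted p = 0.152; fry adjusted p = 0.0272, down). Of these, POLR1C, BYSL and CAD did not pass without control replicate 1 (limma adjusted p = 0.0537, 0.0694 and 0.0887), nor NOP2 and CAD without control replicate 2 (0.0658 and 0.0551). The 55 ribosomal protein genes had a median of -0.09, with 2 up, both on chromosome 16, and 4 down (0 and 0 adjusted over the list alone; camera adjusted p = 0.213).

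Regulatory and stress lists beyond these moved both ways, with camera adjusted p from 0.601 to 0.963. Among 16 hypoxia genes 6 rose and 4 fell (6 and 6 adjusted over the list alone), with BHLHE40, a transcriptional repressor gene, 2.52-fold lower, NDRG1 1.60-fold lower and ADM, encoding adrenomedullin, 1.70-fold higher. Of 23 chromatin and repressor complex genes 4 rose and 5 fell with either adjustment, EZH2, the histone H3 methyltransferase gene, and RBBP4 rising by 0.77 and 0.84 and GATAD2B and HDAC6 falling by 0.81 and 0.70. The TGF-beta and BMP list held 2 genes higher and 4 lower of 12, with either adjustment, among them BAMBI at 0.83 and ID2 at -0.79. Of 26 unfolded protein and amino acid response genes 8 rose and 5 fell (8 and 6 adjusted over the list alone), with PSPH, of serine synthesis, 1.85-fold higher and DDIT3 1.60-fold lower. Of 27 autophagy and lysosome genes 9 rose and 4 fell (10 and 6 adjusted over the list alone; fry adjusted p = 0.0273, up), with CTSB, encoding cathepsin B, 1.54-fold higher. The lists of oxidative stress, fatty acid, stem and progenitor and antigen presentation genes held 3, 1, 2 and 1 genes higher and 3, 3, 2 and 2 lower, or, adjusted over the list alone, 3, 1, 3 and 1 higher and 3, 2, 2 and 2 lower.

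Lists of markers of other cell types did not pass camera where they could be tested. Of 12 measured myeloid and monocyte genes 3 rose and 2 fell, with both adjustments (camera adjusted p = 0.66), and LYZ, encoding lysozyme, was 3.68-fold higher (log2 1.88, or 1.21 with the mean of its probes). CD14 was at least 1.32-fold higher and SPI1 1.28-fold lower, but neither passed without control replicate 1 (limma adjusted p = 0.0944 and 0.0921) or without control replicate 2 (0.0636 and 0.0879). Of 6 measured megakaryocyte and platelet genes 1 rose and 1 fell (camera adjusted p = 0.914), and of 5 epithelial genes 0 rose and 1 fell (camera adjusted p = 0.732), the counts being the same when adjusted over the list alone. On the lymphocyte list 1 gene was measured and on the fibroblast and stroma list 2, too few to test. Interferon response genes moved both ways, 6 up and 4 down of 15 with either adjustment (camera adjusted p = 0.573), with IFI6 1.86-fold and BST2 1.61-fold higher and ISG15 2.14-fold lower. Among 14 housekeeping genes 1 rose and 3 fell with either adjustment (camera adjusted p = 0.896), and HPRT1 rose by 0.66.

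Gene position was related to the change, a pattern noticed after the data were seen. The 458 tested genes of chromosome 16 had a median log2 fold change of 0.36, and 84.7% of them lay above 0, whereas the medians of the other chromosomes lay between -0.11 and 0.03. Of these 458 genes 256 rose and 23 fell, so that chromosome 16 held 13.9% of the genes that rose and 4.81% of the genes tested. Blocks of neighbours shifted together were also found on chromosome 2 from NUP35 to CYP20A1 (54 genes, median -0.50), on chromosome 9 from SURF4 to LINC01451 (24 genes, median -0.45) and on chromosome 7 from ZNF777 to GALNT11 (23 genes, median 0.39). Without the 559 genes of chromosome 16 and these blocks, 1555 genes rose and 1871 fell. The globin, red cell membrane, BCR-ABL and STAT5 and histone lists then still passed camera, with adjusted p of 0.00209, 2.34e-05, 0.0136 and 0.00684. The heme list then passed as well (camera adjusted p = 0.0432). The red cell membrane, histone and heme lists lost no member, so for them only the genes compared with changed. The median of all tested genes was -0.0278 in this run, against -0.0145 before. With an estimated correlation none of the lists passed camera in these genes either, the smallest adjusted p being 0.57 and the smallest unadjusted p 0.0627.

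**Figure D3:**
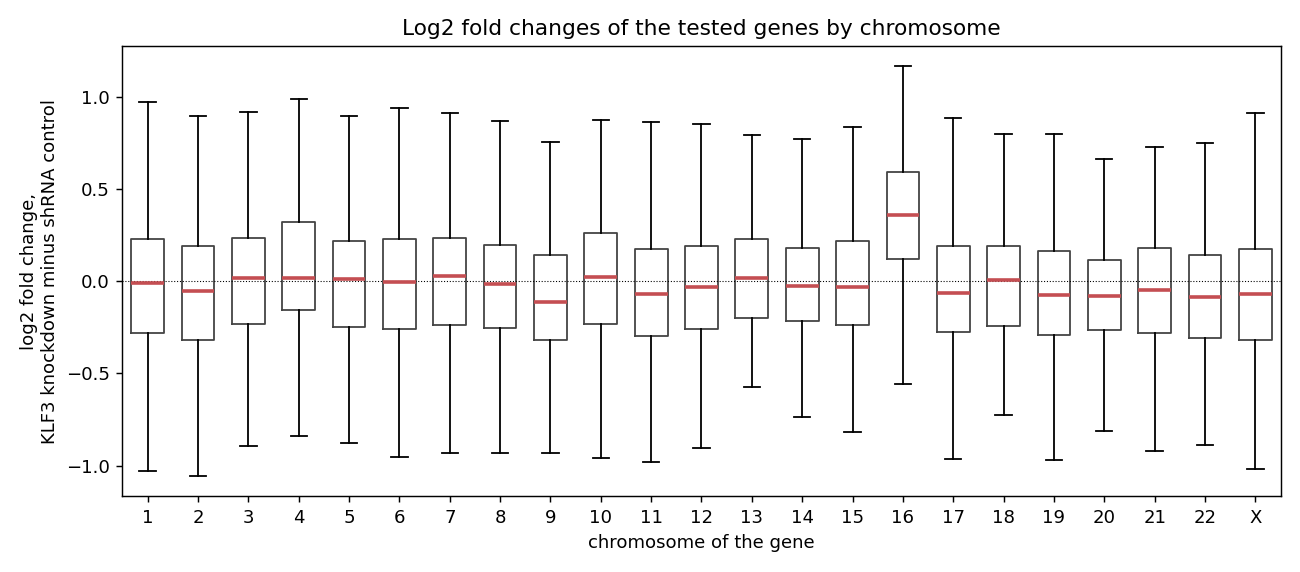
Log2 fold change of the tested genes by chromosome, with boxes for the middle of the genes from the lower to the upper quartile, red bars for the median and whiskers to the last gene within 1.5 times the box height; genes beyond are not drawn. The chromosome 16 median of 0.36 stands above those of the other chromosomes, which lie between -0.11 and 0.03.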

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

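Probes without a single gene name were left out of the gene comparison and examined only after the other results were seen. Of 3261 such probes detected in a group, 1041 changed in limma with Benjamini-Hochberg adjustment over all kept probes, 501 of them higher and 540 lower in the KLF3 knockdown line, and 72 by at least 2-fold. What these probes measure was not analysed here.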

How the results depend on the processing

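The run without chromosome 16 and the shifted blocks was chosen after seeing the data; the other settings were not. None of the 156 genes named by rule changed direction in any alternative run that measured it. Of these gene values 2504 kept their side of the threshold, 100 lost it and 7 gained it. Genes named after their values were seen were not followed through these runs. Losses were most frequent without a control array, 31 without replicate 1 and 28 without replicate 2. HBG2 passed in 7 runs. Alternatives that kept the number of changed genes within 1.5 times gave 3071 to 4513 in place of 3816, under which 5 to 8 lists passed in place of 5. Leaving out 1 array gave 1720 to 3464 changed genes, 852 to 1683 higher and 868 to 1781 lower, and 5 to 6 lists. With 1 array left in a group, that array was assumed to vary like the other group's, and without a control array the spread came from the knockdown pair alone, at 1 residual degree of freedom. Of the genes changed without control replicate 1, 1669 were shared with the 3816, and 1632 without control replicate 2. Without a filter on detection, which raised the genes tested to 20045, 2398 changed, 1189 higher and 1209 lower, of which 2274 were shared, and 11 lists passed; the cause of the larger number of lists was not tested. Stricter thresholds on fitted folds or adjusted p left fewer genes by construction: 1317 at 1.5-fold (650 higher, 667 lower), 317 at 2-fold (153 and 164) and 1813 at an adjusted p under 0.01 (899 and 914). Lists past the threshold numbered 8 without background correction, 8 with the series matrix values and 8 with an intensity trend; the cause was not tested. With an estimated correlation, on 2 residual degrees of freedom, 0 lists passed camera, the smallest unadjusted p being 0.0522. In contrast 14 passed fry, which tests whether a list's genes move one way and not whether they differ from other genes. The 5 passing lists otherwise kept direction and threshold, except the actin and adhesion list without chromosome 16 and the blocks. The word Repeat gave no pairing: replicate differences in the 2 groups correlated at -0.006 across genes, and with the replicate block 3554 genes changed, 1724 higher and 1830 lower. No alternative gave a KLF3 value to report, because KLF3 was not well above background. Signal over background limits dim genes: 366 tested genes were undetected in 1 group and have only a bound there, and folds without background correction are smaller, with 94 genes at 2-fold in place of 317.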

Other observations

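All gene families and single genes in this paragraph were chosen after the values were seen. S100A4, a calcium-binding protein gene, rose by 2.19 on the log2 scale, and RUNX1, a hematopoietic transcription factor gene, fell by 1.07, both past the limma adjusted threshold. Of 12 measured genes of the TNF receptor and ligand families 3 rose and 7 fell (median -0.39), and of 45 tubulin and kinesin genes 6 rose and 14 fell (median -0.16). Among 291 zinc finger (ZNF) genes 48 rose and 54 fell, with ZNF680 at least 2.43-fold and ZNF425 3.38-fold higher. None of the 12 families examined passed camera, the smallest adjusted p being 0.539. Probes of 1 gene went opposite ways for 26 of 2399 genes with several kept probes, among them MSI2, whose probes gave -0.82 and 0.81, and CREB1, CLOCK and AGO3.

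In the following patterns the tests on GC-rich chromosomes, on chromosome 16 copies as the cause of the erythroid change, on bright probes and on the alpha-like globins were chosen after the result was seen; an earlier test that asked each of the 4 alpha-like globins to lie beyond other chromosome 16 genes gave no decision. Chromosome 16 genes had a median log2 fold change of 0.36. A general bias of GC-rich chromosomes is argued against by the median of chromosomes 17, 19 and 22, -0.0759 (95% bootstrap interval -0.10 to -0.05). The difference from other genes was 0.38 (0.34 to 0.42) under median scaling, against 0.39 with quantile normalization. Neither method uses gene position, so this comparison could hardly have come out otherwise and says little about an effect of normalization. Bootstrap intervals here and below resample genes as if they were independent. They do not measure the spread between arrays or lines. The shift held in each of 4 stretches of the chromosome and among its dimmer and its brighter genes. These medians lay between 0.28 and 0.42, which a copy-number difference between the lines could give. For scale, 4 copies against 3 would give 0.42 and 3 against 2 would give 0.58. The chromosome 16 median depended on the processing, however. It was 0.22 without background correction, 0.23 with the series matrix values, 0.30 with an offset of 50 and 0.37 with cyclic loess. No copy ratio can therefore be read from its size. The copy numbers of the 2 lines were not measured. A candidate explanation for the blocks on chromosomes 2, 7 and 9 is of the same kind, but DNA was not analysed here, and an effect of KLF3 depletion stays open and untested because each group is 1 line.

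Erythroid genes were higher in the knockdown line, with a median of 0.68 over 41 measured members of the globin, red cell membrane and heme lists. These lists were pooled after their values were seen. The pool leaves out the erythroid transcription factor list, of which 7 genes rose and 7 fell of 21 (median 0.19). The heme list did not pass camera (adjusted p = 0.0652), and none of the 3 lists passed with an estimated correlation (adjusted p = 0.503 each). The rise was not confined to chromosome 16, since the 37 members outside it and the shifted blocks were higher too. Their median was 0.54 (95% bootstrap interval over genes 0.24 to 0.80), with HBB at its fitted value. Extra copies acting only on chromosome 16 genes would not, by definition, raise these members. Because the lists were pooled after their values were seen, this median describes them and is no independent test. Whether extra copies also changed genes elsewhere was not tested. A general rise of probes of middling brightness is argued against by 3852 other genes as bright as the middle of the 41 members. Their median without normalization between arrays was -0.0721 (-0.09 to -0.06), against 0.64 for the 41 members. Members brighter than that middle, such as HBG1 and HBG2, were not matched. The hypothesis that KLF3 depletion raised erythroid genes stays open beside a difference between the lines or in culture state, since neither was tested and KLF3 itself was not measured.

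The 4 alpha-like globin genes HBZ, HBA1, HBA2 and HBQ1 had a median of 1.504, and 3 of them lay above 1.13. That value is the upper end of the middle 95% of single other chromosome 16 genes. A shift of the size seen along the chromosome is therefore argued against as the whole cause of their rise as a group. Whether extra copies raised them in another way was not tested. HBQ1, at 0.78, lay within the range of the other chromosome 16 genes, and for it alone the shift may suffice. A gain that reaches the 25 measured neighbours of the cluster is argued against as the whole cause by their median of 0.42 (95% bootstrap interval 0.25 to 0.63). A gain of the cluster alone was not tested, and what raised these genes further stays open, with KLF3 depletion among the untested explanations.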
